A study of Mus musculus with 10 samples.

How the data were processed

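The samples were RNA from sorted lung endothelial cells of mice with loxP-flanked Tnfsf10, the gene of the death ligand TRAIL. One group also carried a tamoxifen-inducible Cre recombinase driven by the endothelial Cdh5 promoter. Per the labels' protocols, animals were 8 to 14 weeks old and received 1 mg tamoxifen per day for 5 or 10 days, RNA was isolated with TRIzol, and poly-adenylated RNA was made into libraries with a stranded mRNA kit. The labels name 5 controls without the Cre transgene and 5 libraries with it, called EC-TRAIL KO. The series' design text names 4 transgenic animals, where the sample labels and the count table hold 5. Which library the text leaves out is not stated, and all 5 were used. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these libraries.

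Per the submitters' processing notes, the tools were STAR 2.7.1a and RSEM 1.2.28 and the genome build was GRCm38. The deposited table holds expected counts per gene as RSEM estimates them, with no normalization, and 81.2% of its values are whole numbers. The authors' gene annotation release, filters and strand setting are not given in the sources used here. The table has 55385 gene identifiers. All 10 columns were matched to samples by their titles. Gene symbols and positions came from the GENCODE annotation of GRCm38, in which 55144 identifiers matched without their version, 54487 also matched with it, and 241 did not match. An expected count divides reads among near-identical genes by a model, so values of pseudogenes, of paralogs such as H2-Q6 and H2-Q7, and of antisense genes are uncertain.

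The expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with its minimum count of 10, which left 17997 genes and removed 37388. Library sizes were scaled by TMM, and the groups were compared with edgeR's quasi-likelihood F-test in its default estimation, with group as the only term. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. CPM values used the TMM library sizes. The standard error of a log2 fold change was taken as its size divided by the square root of F. Log2 CPM for list means used a prior count of 2. The median log2 fold change over all genes was -0.0085 under TMM and -0.00611 with library size only.

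Library totals ran from 29806083 to 56897822 expected counts. A gene at 0 counts in a library is compatible with up to 3 counts, and such floors cover counting error only. Counts were simulated with the depths of this comparison, and the changed genes were drawn from those with a mean CPM of at least 1. With 17723 genes tested, the test recovered 47.8% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 100% of those changed 4-fold. There were 8 false calls among 161. Recovery of genes below that mean was not measured. No other list was called when the NF-kB list was raised in simulated counts. The simulated genes were drawn independently of each other, so this does not test false list calls where real genes of a list vary together. The lowest chi-square per degree of freedom between any pair of libraries was 20.6, so no library appeared to be deposited more than once.

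Before the data were examined, 41 gene lists, the main test apart from its estimation setting, the rule for naming genes and most alternatives were fixed. One list, of sex-linked genes, served as a check only. The other 40 lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation, fry and an exact two-sided permutation of each list's mean over the 252 assignments of the libraries were also run. Among the lists called with the preset, the estimated correlation ran from 0.0706 (p53 targets) to 0.837 (proliferation), above the preset in each. If the estimates hold, p-values with the preset are too small for these lists. Intervals of list differences hold the shifts that this exact test does not exclude at 95% confidence, a method chosen after seeing the data. The named genes are the members of the TRAIL pathway list, the 12 genes with the smallest p in each direction among those passing (or, where fewer than 5 pass, the 5 with the smallest p, named as not passing), and up to 4 members of each list, being those that passed and, for called lists and markers of other cell types, those with the smallest p. Predicted genes and pseudogenes were skipped in the second part. Gm8748, Gm13217, Gm29682, Cdh5, Sftpc, Ptprc, Cdkn1a, Mdm2, Ccng1, Gdf15, Pcna, E2f1, Tk1 and the clock genes were named after their values were seen.

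The alternatives fixed in advance were RLE factors, library size only, limma-voom with and without sample quality weights, no low-count filter, a mean CPM of at least 1, the replicate number as a block, each library left out in turn, the mean of the markers of other cell types as a covariate, DESeq2 1.42.0 and an adjusted p threshold of 0.1. Sex as a covariate was not run, because every library had at least 25138 counts of Xist and at most 12 of any Y-linked gene examined. Chosen after seeing the data were edgeR's bias-adjusted quasi-likelihood estimation, counts thinned to the smallest library total, a fit without both libraries numbered 4, and the permutation of list means. The estimation setting of the main test was not fixed in advance either. The bias-adjusted estimation was run first, and the package default was then taken as the main one.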

Results

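RNA sequencing measured gene expression in sorted lung endothelial cells from mice with loxP-flanked Tnfsf10, which encodes the TNF-family ligand TRAIL. The control group had no Cdh5-driven Cre (n = 5 libraries), and the group labelled EC-TRAIL KO carried it (n = 5). The comparison asks what differs in lung endothelium when TRAIL is deleted there. Every library labelled EC-TRAIL KO carries the Cre transgene and no control does, so the transgene and the deletion are not separated by this design. Totals ran from 34435835 to 56897822 expected counts in controls and from 29806083 to 34702571 in the libraries labelled EC-TRAIL KO. Depth therefore differed between the groups (exact two-sided permutation p = 0.0159).

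Tnfsf10 (ENSMUSG00000039304, GRCm38 chromosome 3, 27317028 to 27342427, plus strand) was measured first, because it checks the labels. Controls had 373.6, 369.5, 298.2, 323.3 and 304.6 CPM in replicates 1 to 5. The libraries labelled EC-TRAIL KO had 198.9, 318, 126.3, 169.3 and 80.99 CPM. Replicate 2 of that group lay within the control range, at 95.3% of the control mean, while the other 4 lay below every control. The group means were 333.9 ± 35.7 and 178.7 ± 89.7 CPM (SD, n = 5 each), a log2 fold change of -0.90 (SE 0.276). The change did not pass edgeR's quasi-likelihood test over all genes (adjusted p = 0.425). The exact two-sided permutation test of this gene alone gave p = 0.0238. Without the library labelled EC-TRAIL KO replicate 2 the log2 fold change was -1.21 and passed (edgeR adjusted p = 0.0345, in a range of 0.0345 to 0.808 over the 22 alternatives). Gene-level counts include exons outside any deleted part, so residual reads do not measure the share of cells without deletion.

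**Figure D1:**
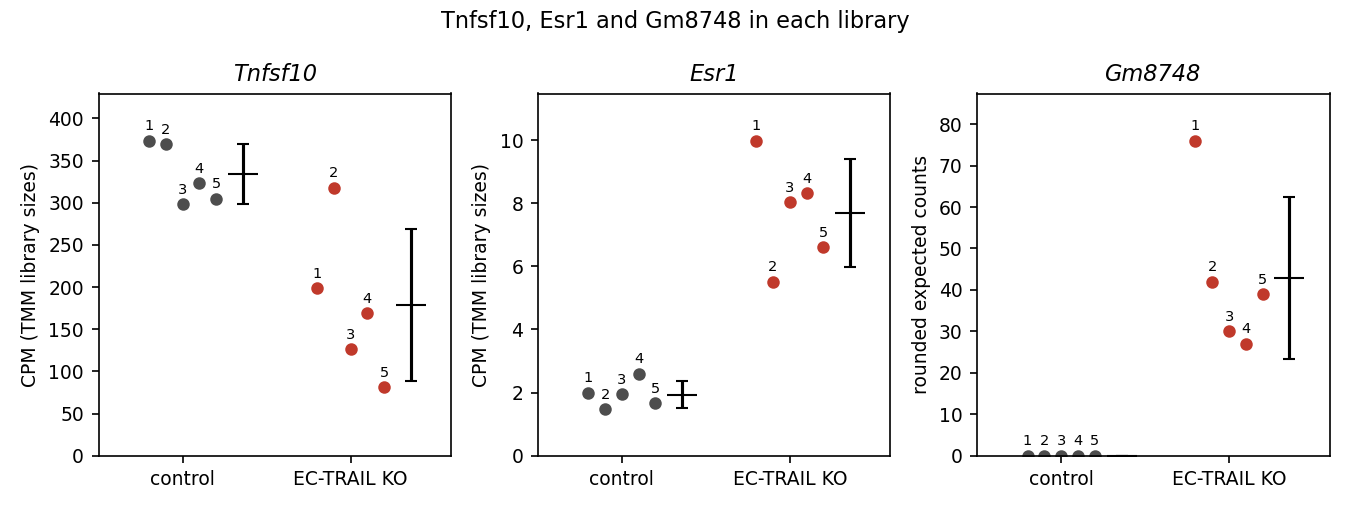
Points are single libraries, numbered by replicate, of the control and EC-TRAIL KO groups; the bar beside each group is the mean with its SD (n = 5). The y axes are CPM for Tnfsf10 and Esr1 and rounded expected counts for Gm8748. Tnfsf10 in EC-TRAIL KO replicate 2 (318 CPM) sits among the controls, whereas Esr1 and Gm8748 are above every control in all 5 EC-TRAIL KO libraries.

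The other 12 members of the TRAIL pathway list did not pass the test, with log2 fold changes from -0.35 to 0.49 and edgeR adjusted p of at least 0.997. With Tnfsf10 included, 0 of 13 passed adjusted over the list alone, and the list was not called (median log2 fold change 0.06, camera adjusted p = 0.893). Tnfrsf10b, the mouse TRAIL death receptor, had 33.7 ± 11.2 CPM in controls and 47.3 ± 33.9 CPM in the libraries labelled EC-TRAIL KO (SD, n = 5 each), with 105.6 CPM in replicate 4 of the latter. The decoy receptors Tnfrsf22 and Tnfrsf23 had log2 fold changes of 0.07 and 0.28, Tnfrsf26 0.11, and Tnfrsf11b, which encodes osteoprotegerin, -0.35. Among the signalling components, Casp8 had -0.0054, Cflar, which encodes the caspase-8 inhibitor c-FLIP, -0.025, and Fadd 0.08. Ripk1 had 0.06, Traf2 0.03, Bid 0.29 and Tradd 0.00017. The signs of Casp8, Cflar, Fadd, Tradd, Traf2, Tnfrsf26 and Tnfrsf10b turned in at least 1 alternative.

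Members of the proliferation list were higher in the libraries labelled EC-TRAIL KO. Top2a, the DNA topoisomerase of dividing cells (ENSMUSG00000020914, chromosome 11, 98992943 to 99024189, minus strand), was at 16.2 ± 4.26 CPM in controls and 82.4 ± 53.01 CPM in the libraries labelled EC-TRAIL KO (SD, n = 5 each), 5.07-fold higher. The kinetochore genes Cenpf and Cenpe were 6.07-fold and 4.61-fold higher, and Ube2c, of the anaphase-promoting machinery, 3.69-fold. Outside the list, 7 genes among those with the smallest p, known from the mitotic spindle or cell division, rose, with Kif2c 5.66-fold, Kifc1 5.20-fold, Tpx2 5.20-fold, Dlgap5 5.37-fold, Hmmr 4.87-fold, Kif23 4.68-fold and Gtse1 4.04-fold (edgeR adjusted p = 0.0432 for each of these 11 genes). In each of them all 5 libraries labelled EC-TRAIL KO, replicate 2 included, lay above all 5 controls, and replicate 2 had the highest value (Top2a 170.2 CPM).

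**Figure D2:**
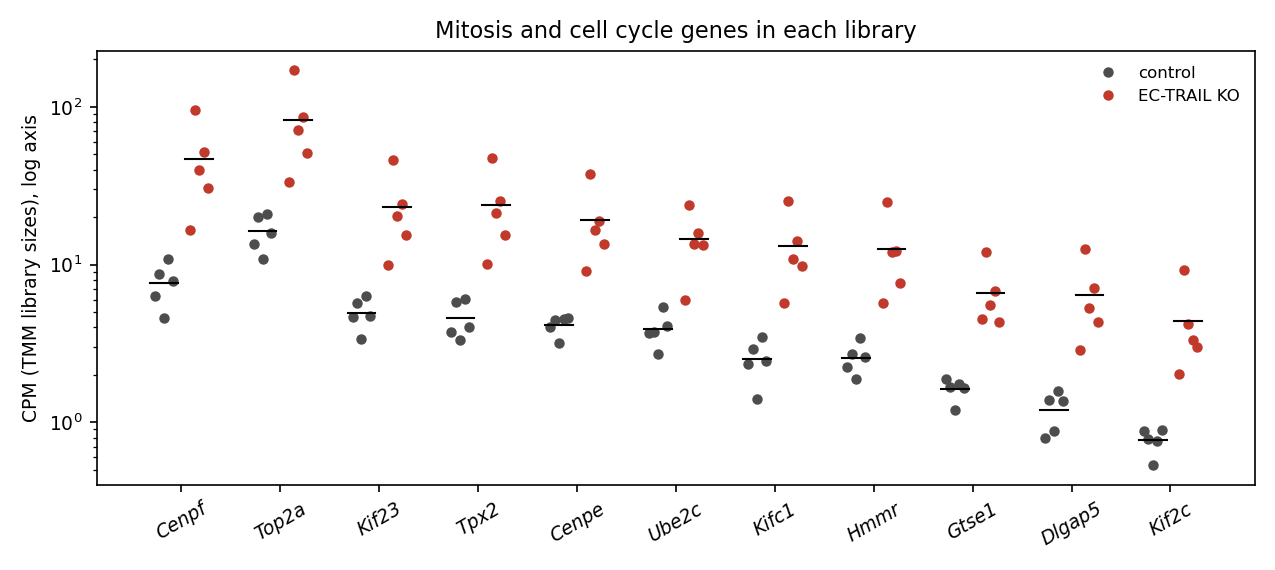
Each point is 1 library and each line a group mean (n = 5), for 11 genes of mitosis and the cell cycle named by the rule; the y axis is CPM on a log scale. For every gene the EC-TRAIL KO points lie above the control points, for example Cenpf at 16.5 to 95.02 CPM against 4.62 to 10.9 CPM.

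Of the 24 tested members of the proliferation list, 14 rose, none fell and 10 did not pass. When adjusted over the list alone, 23 passed. The size of the rise differed between members, with the smallest log2 fold change, 0.03, in Pcna (edgeR adjusted p = 0.997). E2f1 was at 0.65 (edgeR adjusted p = 0.944) and Tk1 at 0.81 (edgeR adjusted p = 0.0863). Pcna, E2f1 and Tk1 were named after their values were seen. The median log2 fold change of the list was 1.85, and 20 members had all libraries labelled EC-TRAIL KO above all controls. Camera with the preset correlation gave adjusted p = 4.63e-41. With the estimated correlation, which was 0.837, the list did not pass (camera adjusted p = 0.191), nor did it with fry (adjusted p = 0.088). The mean log2 CPM of the list was 2.50 ± 0.277 in controls and 4.02 ± 0.706 in the libraries labelled EC-TRAIL KO (SD, n = 5 each), a difference of 1.53 (95% interval 0.766 to 2.36). The exact permutation p of this mean was 0.00794, the smallest that 5 against 5 libraries can give, and 0.159 after adjustment over the 40 lists. At that floor a list cannot pass the adjustment unless several lists reach the floor together, so this miss decides nothing.

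In all, 79 of 17997 tested genes were higher in the libraries labelled EC-TRAIL KO and 0 were lower (edgeR quasi-likelihood, adjusted p under 0.05). At an unadjusted p under 0.05, 686 were higher and 237 lower. Together these are close to the share of 0.05 of tested genes that chance alone gives, so their total does not show a difference. DESeq2 called 208 higher and 3 lower. Of the 79 genes, 77 had an adjusted p between 0.04 and 0.05, so nearly the whole count lay close to the threshold. Leaving out any 1 of the 5 controls, or the library labelled EC-TRAIL KO replicate 3 or replicate 4, left 2 genes, Esr1 and Gm8748, and no member of the proliferation list passed; without replicate 1 of that group 154 passed. The same 2 genes alone passed with limma-voom, with and without quality weights, and with library size only, and Esr1 alone passed with the marker mean of other cell types as a covariate or without both libraries numbered 4. In the settings that left 1 or 2 genes, the 11 genes named above had log2 fold changes of 1.71 to 2.76, against 1.88 to 2.60 in the full comparison. With the covariate Top2a was at 2.40 (SE 0.457, edgeR adjusted p = 0.209) against 2.34 (SE 0.374). In that fit the call ended with a larger error and not with a smaller fold. With quality weights Top2a was at 2.04 (SE 0.353, limma-voom adjusted p = 0.108), so there the fold was smaller and the error was not larger. The proliferation list had a median of 1.5 to 2.03 over 23 settings and was called in 20, the exceptions being the 3 other list tests. All 20 calls used camera with the preset correlation of 0.01, so they do not back that assumption. Over all tested genes, 1.38% had every library labelled EC-TRAIL KO above every control and 0.261% had the reverse, where chance gives 0.397% in each direction.

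Esr1, the estrogen receptor alpha gene (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614, plus strand), had the smallest p. It was at 1.94 ± 0.429 CPM in controls and 7.69 ± 1.71 CPM in the libraries labelled EC-TRAIL KO (SD, n = 5 each), a log2 fold change of 1.99 (SE 0.196; edgeR adjusted p = 0.00488), and higher in 5 of 5 libraries. It passed in all 22 alternatives, with log2 fold changes from 1.88 to 2.12. It was the single member of the estrogen and tamoxifen response list that passed, also when adjusted over the list alone, among 15 tested. That list was not called (median -0.021, camera adjusted p = 0.893). Gm8748, a processed pseudogene on chromosome 8 (ENSMUSG00000110019, 104071149 to 104071735, plus strand), was outside the naming rule and was chosen after its values were seen. It had 0 counts in all 5 controls and 27 to 76 counts in the libraries labelled EC-TRAIL KO, at least 104-fold higher against a floor of 3 counts over the control group. It lies 29.9 kb from Cdh5, whose promoter drives the Cre transgene. Cdh5 itself was at 3820 ± 292 and 4040 ± 147 CPM (SD, n = 5 each).

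Of 19 tested p53 targets 2 rose, 0 fell and 17 did not pass; 6 passed adjusted over the list alone. Eda2r, a TNF receptor family member, was 3.92-fold higher and Bax, the pro-apoptotic Bcl-2 family member, 1.31-fold higher (edgeR adjusted p = 0.0432 for both). Phlda3 was at 38.7 ± 3.71 and 55.7 ± 7.99 CPM (edgeR adjusted p = 0.0528) and Aen at 16.4 ± 1.99 and 22.7 ± 4.52 CPM (edgeR adjusted p = 0.381; SD, n = 5 each). Cdkn1a, Mdm2, Ccng1 and Gdf15, members chosen after their values were seen, had log2 fold changes of 0.08, 0.10, 0.05 and 1.09 and did not pass (edgeR adjusted p = 0.868 for Gdf15 and 0.997 for the others). Camera gave the list adjusted p = 3.46e-05, and adjusted p = 0.191 with an estimated correlation. Fry gave adjusted p = 0.088. The exact permutation of the list mean gave p = 0.00794, the smallest possible, and 0.159 after adjustment. The calls of Eda2r and Bax were lost in each setting that left Esr1 with or without Gm8748, among them the removal of any 1 control or of the library labelled EC-TRAIL KO replicate 3 or 4; that of Bax was also lost without replicate 2 of that group (edgeR adjusted p = 0.0702). Where the calls were lost, the log2 fold change was 1.78 to 2.19 for Eda2r, against 1.97 in the full comparison, and 0.36 to 0.44 for Bax, against 0.39. Bax was the single member of the death receptor and extrinsic apoptosis list that passed, also when adjusted over the list alone, among 18 tested (median 0.07, camera adjusted p = 0.0863).

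Antigen presentation and inflammatory lists had no member that passed, and 0 passed in each of them when adjusted over the list alone. All 15 members of the MHC class I presentation list had a log2 fold change above 0, with a median of 0.12 and with Nlrc5, its transcriptional activator, at 0.27, H2-Q7 at 0.28, H2-Q6 at 0.31 and Tap1, the peptide transporter, at 0.21 (camera adjusted p = 4.85e-05; adjusted p = 0.825 with an estimated correlation). The type I interferon response list had a median of 0.11, with Oas1a at 0.35, Oas2 at 0.47, Rsad2 at 0.39 and Zbp1 at 0.39 (camera adjusted p = 0.00659; 0.825 with an estimated correlation); the call was lost without control replicate 2 or 4 or the library labelled EC-TRAIL KO replicate 1 (adjusted p = 0.0532 to 0.203) and with the marker mean of other cell types as a covariate (median 0.09, adjusted p = 0.0798). The NF-kB target list had a median of 0.25, with Nfkbie at 0.63, Tnip1 at 0.37, Sele, the endothelial selectin, at 0.68 and Cxcl1 at 0.39 (camera adjusted p = 0.00659; 0.825 with an estimated correlation), and lost its call without control replicate 3 or the library labelled EC-TRAIL KO replicate 4 (adjusted p = 0.0532 and 0.241). The endothelial chemokine list had a median of 0.28, with Cxcl9 at 0.86, Ccl5 at 0.74 and Ackr3 at 0.26 (camera adjusted p = 0.0333; 0.825 with an estimated correlation). The chemokine list shares members with the NF-kB list, Cxcl1 among them, so the calls of these lists are not independent. The chemokine call was lost without control replicate 3 or 5 or the library labelled EC-TRAIL KO replicate 1, 2 or 4 (adjusted p = 0.0814 to 0.342), with quality weights (0.112) and at a mean CPM of at least 1 (0.0755). The lymphatic endothelium list had a median of 0.26, with Maf at 0.35, Reln at 0.38, Flt4 at 0.17 and Prox1, the lymphatic transcription factor, at 0.50 (camera adjusted p = 0.0348; 0.825 with an estimated correlation). Its call was lost without any 1 of replicates 1 to 3 of either group (adjusted p = 0.0724 to 0.171). It was also lost with the replicate number as a block (camera adjusted p = 0.126), at a mean CPM of at least 1 (0.0585) and with the marker covariate (0.0868).

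Markers of other cell types were present in every library. Sftpc, a surfactant gene of alveolar type II cells, was at 4377 ± 1045 CPM in controls and 4064 ± 472 CPM in the libraries labelled EC-TRAIL KO (SD, n = 5 each), and Lyz2, of macrophages and alveolar cells, at 1404 ± 279 and 1267 ± 180 CPM. Ptprc, the pan-leukocyte gene, was at 3.32 ± 1.19 and 3.24 ± 0.912 CPM. The alveolar epithelial list had a median log2 fold change of -0.11, with Epcam at -0.22, Lamp3 at -0.21, Cdh1 at -0.18 and Cldn18 at -0.16 (camera adjusted p = 0.0333; 0.878 with an estimated correlation). The fibroblast list had a median of -0.15, with Scube2 at -0.35, Fmo2 at -0.23, Col14a1 at -0.17 and Eln, in the opposite direction, at 0.29 (camera adjusted p = 0.0348; 0.878 with an estimated correlation). No member of either list passed, also when adjusted over the list alone. The alveolar call was lost without control replicate 2 or 5 or the library labelled EC-TRAIL KO replicate 1, 2 or 3 (adjusted p = 0.0724 to 0.715). The fibroblast call was lost without control replicate 2, 3 or 4 or the library labelled EC-TRAIL KO replicate 1 or 2 (adjusted p = 0.0959 to 0.692). It was also lost with quality weights (camera adjusted p = 0.181) and at a mean CPM of at least 1 (0.0558). Both calls were lost with the replicate number as a block (alveolar 0.0969, fibroblast 0.0747) and with the marker covariate (0.653 and 0.409). The library labelled EC-TRAIL KO replicate 2, which had the highest mean of the proliferation list, had the lowest mean log2 CPM of both lists among the 10 libraries (6.91 alveolar and 5.37 fibroblast). Pericyte and smooth muscle markers had a median of -0.12, with Gucy1a1 at -0.34, Trpc6 at -0.29, Pdgfrb at -0.24 and Notch3 at -0.22, and were not called (camera adjusted p = 0.0961). Macrophage and monocyte markers (median -0.06), neutrophil markers (-0.15), T, NK and B cell markers (0.03) and platelet and erythroid markers (-0.22) were not called either. Among their members Mrc1 had 0.61, Ctss 0.49, Tyrobp -0.39, Hdc -0.16, Cxcr2 -0.43, Ltf -0.15, Il1b 0.22, Pax5 0.44, Cd2 -0.22, Lck 0.26, Cd79a 0.18, Alas2 0.53, Pf4 -0.68, Ppbp -0.65 and Hbb-bt -0.41, none passing. The signs of Tyrobp, Cxcr2, Il1b, Pf4 and Ppbp turned in at least 1 alternative.

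**Figure D3:**
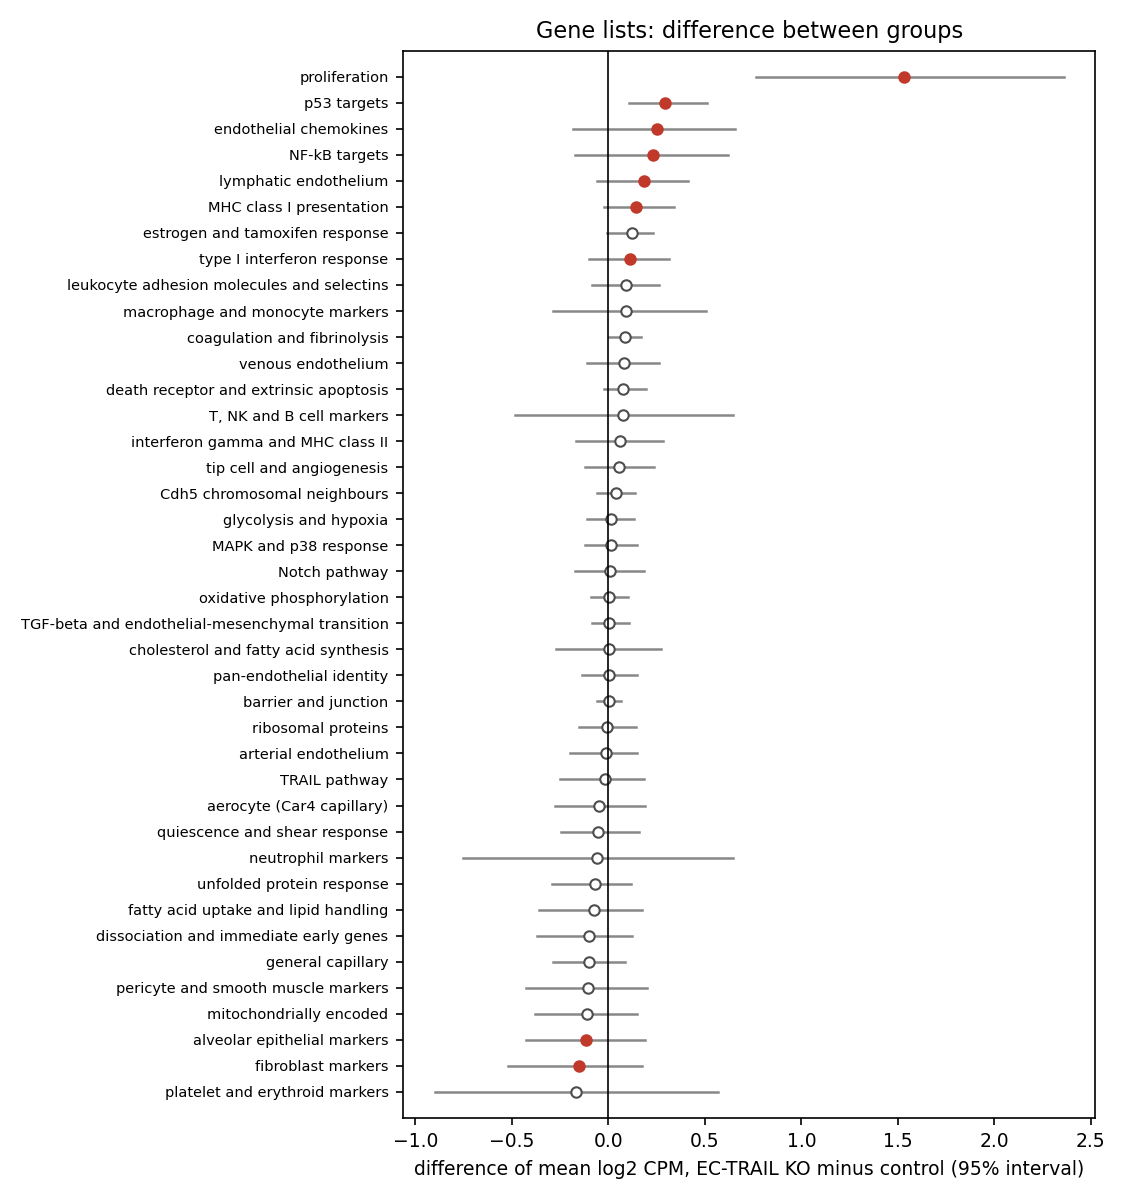
Each row is a gene list, and the point is the difference of its mean log2 CPM, EC-TRAIL KO minus control (n = 5 each), with the 95% interval from the exact permutation test. Filled points are lists called by camera with the preset correlation; the proliferation list lies at 1.53 and every other list between -0.169 and 0.292.

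Endothelial identity was measured with lists of vascular beds and functions, and 31 of the 40 lists were not called, with medians between -0.22 and 0.09 and camera adjusted p of at least 0.0678. Besides the lists of other cell types and the TRAIL, extrinsic apoptosis and estrogen lists above, these were pan-endothelial identity (median log2 fold change 0.04), barrier and junction (0.02), quiescence and shear response (-0.07), tip cell and angiogenesis (0.05), the Notch pathway (0.0096), TGF-beta and endothelial-mesenchymal transition (-0.026), coagulation and fibrinolysis (0.09), leukocyte adhesion molecules and selectins (0.08), aerocytes (-0.035), general capillaries (-0.13), arterial (-0.013) and venous endothelium (0.06). Stress and metabolic lists were also among them, namely the unfolded protein response (-0.035), the MAPK and p38 response (-0.05), dissociation and immediate early genes (-0.15), interferon gamma and MHC class II (0.08), glycolysis and hypoxia (0.02), oxidative phosphorylation (0.0027), cholesterol and fatty acid synthesis (-0.0040), fatty acid uptake (-0.10), ribosomal proteins (0.0092), mitochondrially encoded genes (-0.12) and the chromosomal neighbours of Cdh5 (-0.0044). No member of these lists passed adjusted over the list alone, apart from Bax and Esr1 above. The median, the difference of means and the direction of the test differed in sign for the TRAIL, MAPK and p38, barrier, TGF-beta, macrophage, cholesterol, estrogen and ribosomal lists and the neighbours of Cdh5. A miss of the threshold does not show that a list was equal in both groups. The exact interval of the difference for pan-endothelial identity was -0.138 to 0.147 and for barrier and junction -0.0588 to 0.0633.

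No gene was called lower. The 5 named genes with the smallest p in that direction did not pass; they were Slc5a12, a monocarboxylate transporter, with a log2 fold change of -0.50 (edgeR adjusted p = 0.0832), Pcdh18 with -0.36 (0.167), Ctnnd2 with -0.53 (0.256), Hs6st2 with -0.86 (0.268) and Pcdha4 with -1.27 (0.288). In each of them all 5 libraries labelled EC-TRAIL KO lay below all 5 controls. Slc5a12 passed without the library labelled EC-TRAIL KO replicate 1 (edgeR adjusted p = 0.0369), and Slc5a12, Pcdh18 and Ctnnd2 passed with DESeq2.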

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

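The values below stood apart from the other libraries of their group by Dixon's ratio, above its critical value of 0.71 for 5 libraries; 9 of the 184 groups examined did so, and chance gives about 1 in 20. The correlation below was chosen after the data were seen.

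In control replicate 4, Ppbp was at 19.1 CPM against 2.95 to 4.47 CPM in the other controls, Pf4, also a platelet gene, at 3.45 CPM against 0.704 to 0.962, Eln at 340 CPM against 253 to 278 and Bax at 39.2 CPM against 33.4 to 35.0. In the library labelled EC-TRAIL KO replicate 4, the TRAIL receptor gene Tnfrsf10b was at 106 CPM against 17.1 to 41.6 in the others of its group, Cxcl1 at 7.24 CPM against 3.32 to 4.41, and Cflar at 197 CPM, below 243 to 260. Epcam was at 20.5 CPM in control replicate 2 against 15.8 to 17.1, and Ltf at 1.83 CPM in the library labelled EC-TRAIL KO replicate 5 against 0.763 to 1.05.

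Of these 9 values, 7 belong to the libraries numbered 4, which also lay apart from the rest on the second principal component (-35.4 and -45.7, where the other libraries ran from -8.71 to 25.7). The deviations of these 2 libraries from their group means correlated across the tested genes, which are not independent replicates (r = 0.433). Whether they share a day or a time of collection cannot be told apart from other causes here, because the labels give neither and the libraries numbered 2 reached only r = 0.0679.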

How the results depend on the processing

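Chosen after seeing the data were the bias-adjusted estimation, the thinned counts, the fit without both libraries numbered 4 and the permutation of list means; the other settings were fixed in advance, and for values that changed the cause was not tested unless stated. The count of 79 higher genes became 2 with library size only, 2 with limma-voom, 2 with its quality weights, 1 with the marker covariate and 1 without both libraries numbered 4, and rose to 208 with DESeq2, 141 without a low-count filter and 129 at an adjusted p under 0.1, where the looser threshold is the cause. Leaving out 1 library gave 2 to 154. The genes left were Esr1 and Gm8748, or Esr1 alone. With library size only the 11 mitosis and cell cycle genes named above narrowly missed the threshold (edgeR adjusted p = 0.0501 for each). Top2a kept its log2 fold change of 2.34 there. Lower genes went from 0 to 3 with DESeq2, 2 without a filter (Gm13217 and Gm28048, named after their values were seen), 1 at an adjusted p under 0.1, and 0 to 1 when 1 library was left out (Slc5a12, Tnfsf10 or, named after its values were seen, Gm11914).

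Tnfsf10 kept its direction in all 22 settings and passed in 1, with log2 fold changes from -1.21 to -0.717 when 1 library was left out. The 7 higher lists became 0 with an estimated correlation, 0 with fry and 0 with the permutation of list means, 5 at a mean CPM of at least 1 (losing the chemokine list, adjusted p = 0.0755, and the lymphatic list, 0.0585) and 5 with the marker covariate (losing the type I interferon list, whose median went from 0.11 to 0.09, adjusted p = 0.0798, and the lymphatic list, from 0.26 to 0.31, adjusted p = 0.0868); with quality weights the chemokine list lost its call (0.112). Leaving out 1 library gave 4 to 9, with 4 without the library labelled EC-TRAIL KO replicate 1. The 2 lower lists became 0 with each of these 3 tests and without a filter, 1 with quality weights and 1 at a mean CPM of at least 1. With the marker covariate the alveolar and fibroblast lists both lost their call (adjusted p = 0.653 for the alveolar and 0.409 for the fibroblast list) and 2 other lists were called. The covariate contains the markers of both lists, so this loss was partly built in. Leaving out 1 library gave 0 to 5 lower lists, with 0 without the library labelled EC-TRAIL KO replicate 1 or 2 and 5 without control replicate 1. None of the 15 called named genes turned its direction in any of their 329 combinations of gene and setting, and 159 of these lost the call. The settings share libraries, so these combinations are not independent.

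The replicate number as a block gave 146 higher and 3 lower genes (Dnajb9, Gm44220 and Kif26b, named after their values were seen), with Tnfsf10 at -1.04 (edgeR adjusted p = 0.0513) and Phlda3 passing (0.0129). Under the block 6 lists were called higher, the lymphatic list losing its call (adjusted p = 0.126), as did the alveolar (0.0969) and fibroblast lists (0.0747), while 2 other lists were called lower. The labels do not say that the numbers pair the animals, and 4 of the 5 same-numbered correlations of deviations were over 0.1 (0.0679 to 0.433). In each group 4 of 5 libraries correlated best with their own number, a hint from the data and not from the design.

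Genes that did not pass changed sign in 39 combinations of gene and setting in all. Tradd was at -0.0097 with limma-voom, -0.039 with quality weights, -0.013 without a filter, -0.00066 at a mean CPM of at least 1, -0.0068 with the marker covariate, -0.0024 with DESeq2, -0.0032 with bias-adjusted estimation, -0.030 when thinned and -0.018 without both libraries numbered 4. Casp8 was at 0.018 with quality weights, 0.0027 when thinned and 0.016 without both libraries numbered 4, Cflar at 0.0042 and Il1b at -0.091 with quality weights, Tyrobp at 0.013 with limma-voom, Fadd at -0.0051 with the marker covariate and Tnfrsf26 at -0.058 when thinned. Leaving out 1 library gave Tradd -0.041 to 0.041, Casp8 -0.033 to 0.033, Cflar -0.075 to 0.038, Fadd -0.0088 to 0.16, Traf2 -0.010 to 0.066, Tnfrsf26 -0.051 to 0.29, Tnfrsf10b -0.039 to 0.70, Tyrobp -0.71 to 0.021, Cxcr2 -0.90 to 0.024, Pf4 -1.10 to 0.043 and Ppbp -1.03 to 0.19. Tnfrsf10b turned without the library labelled EC-TRAIL KO replicate 4, and Pf4 and Ppbp without control replicate 4.

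Sex as a covariate was not run, since all libraries had Xist counts and almost no Y-linked ones. In simulated counts of this comparison with 17723 genes tested, 47.8% of genes changed 1.5-fold were recovered, among genes with a mean CPM of at least 1.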

Other observations

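All tests in this part except the other splits of the libraries and the fit with the marker covariate were chosen after the results were seen. Of 9 clock genes, chosen after their values were seen, Nr1d1, Per1 and Dbp differed widely within both groups. Dbp was at 3.73 ± 1.38 CPM in controls and 4.30 ± 2.25 CPM in the libraries labelled EC-TRAIL KO (SD, n = 5 each). Arntl varied little (51.1 ± 3.35 CPM in controls and 47.7 ± 5.81 CPM in the libraries labelled EC-TRAIL KO, SD, n = 5 each). Nr1d1, a circadian repressor, was at 107.8 and 66.99 CPM in control replicates 4 and 5 and at 107.2 and 102.7 CPM in the libraries labelled EC-TRAIL KO replicates 4 and 5, against 11 to 23.1 CPM in the other controls and 9.28 to 17.3 CPM in the others labelled EC-TRAIL KO. Per1, also of the clock, was highest in the libraries numbered 4 in both groups (509.2 and 758.5 CPM), while Per2, Per3 and Ciart were lowest in replicate 4 of the libraries labelled EC-TRAIL KO within that group. Nr1d1, Per1 and Dbp did not pass the test between the groups (edgeR adjusted p = 0.997 for each). Their log2 fold changes were 0.16 (SE 0.817), 0.25 (SE 0.302) and 0.20 (SE 0.360). Gm13217 had the reverse of the Gm8748 pattern, with 6 to 7 counts in every control and 0 in every library labelled EC-TRAIL KO. Gm29682, an antisense gene at Cdh5, was at 0.0311 ± 0.0217 CPM in controls and 0.276 ± 0.157 CPM in the libraries labelled EC-TRAIL KO (SD, n = 5 each) and was too low to be tested.

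Chance assignment of libraries to groups was tested with 100 of the 126 splits into 5 and 5. Only 1, the real one, gave as many called genes in both directions together, with 79 against at most 6 in any other. That is 0.01 of the splits drawn, the smallest share this test can give. Of the 79 genes, 70 followed the mean of the proliferation list within groups (r at least 0.8), against 1.55% of other tested genes. The count thus behaves largely as 1 joint pattern and not as 79 separate results. The splits also exchanged libraries freely, although libraries of the same number tended to deviate together. They were run with the main fit only, where 77 of the 79 genes had an edgeR adjusted p between 0.04 and 0.05. With limma-voom or library size only the real grouping gave 2 genes, Esr1 and Gm8748, and the other splits were not run there. For the count in the main fit chance is thus unlikely but not excluded, and for the other fits the splits decide nothing.

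The higher proliferation genes were set against 4 explanations. A depth effect, from the slope of the list mean on library depth within groups, would give 0.196 (95% interval -1.02 to 1.42), below the observed 1.53 though with an upper bound close to it. After thinning all libraries to one depth the difference was still 1.53. Thinning keeps each gene's expected share of a library, so it speaks to counting depth only. It cannot speak to a cause that changed depth and expression together. With the mean of the markers of other cell types as a covariate, the difference of the list mean was 1.58 (95% interval 0.674 to 2.49, a test chosen after the result was seen) and the list was called by camera with the preset correlation (median 1.90, adjusted p = 4.32e-33) with 0 members passing; without the covariate the list had adjusted p = 0.191 with an estimated correlation and 0.088 with fry. The interval, which lies above 0, argues against a shift in that mean as the whole cause. The alveolar median moved from -0.11 to -0.03, but the covariate contains the alveolar markers, so this move was built in and decides nothing. A small share of cycling cells of 1 other type stays open, because the highest upper bound among the 7 marker lists was 0.648 and abundant markers such as Sftpc could hide it. The Cre transgene and the loss of TRAIL cannot be told apart, since the 2 come together; the library labelled EC-TRAIL KO replicate 2, with Tnfsf10 in the control range, had the highest list mean, 2.56 above the control mean, but 1 library does not decide it. An effect of TRAIL loss on endothelial division was not tested apart from the transgene, which needs mice with the Cre and without loxP-flanked Tnfsf10, not analysed here.

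Gm8748 and Esr1 may carry reads of the transgene. Gm8748 was the single gene with at least 5 counts in every library labelled EC-TRAIL KO and at most 1 in any control, and it lies 29.9 kb from Cdh5, where 0.0181% of genes lie within 100 kb, as reads from the transgene or its flanks would need. For Esr1 the lowest library labelled EC-TRAIL KO was 2.12-fold above the highest control, as reads from the estrogen receptor part of the fused Cre would give, but gene-level counts do not say which exons were covered. An induced endogenous Esr1 stays open too, because the rest of its response list differed by -0.0116 (95% interval -0.124 to 0.105) with 6 of 14 members higher, and members that go both ways decide little.

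The library labelled EC-TRAIL KO replicate 2 had Tnfsf10 at the control level and stood apart on the first principal component (57, where the others ran from -29.7 to 18.8), and a control library under a wrong label was considered. It had 42 counts of Gm8748, where every control had 0, and 5.51 CPM of Esr1 against at most 2.60 in controls. Gm8748 was chosen for its counts in every library labelled EC-TRAIL KO, this one included, so its presence here was part of the choice. Esr1 also passed when this library was left out, so its value here was not. The Esr1 value argues against a wrong label only as far as Esr1 marks the transgene, which stays open. Incomplete deletion is a hypothesis that was not tested, since reads over the loxP-flanked part are not used here.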
